A study of Rattus norvegicus with 9 samples.

How the data were processed

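Chondrocytes were isolated from rat cartilage by digestion for 2 h in collagenase II and dermal fibroblasts from skin by digestion for 3 h in collagenase I, both at 0.5 mg/ml and passed through a 100 μm sieve, per the labels' protocols. Chondrocytes were cultured with 10% fetal bovine serum and 1% ITS supplement. The dose and duration of IL-1β and the length of the co-culture are not given in the sources used here. Poly(A) RNA was captured with oligo(dT) beads, fragmented, reverse transcribed with random primers and made into circular single-stranded DNA libraries, per the labels' protocols. These do not say whether strand was kept, so it is unknown whether reads of overlapping and antisense genes could be told apart.

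The authors deposited 1 table of FPKM values, rounded to 2 decimals, for 17588 genes in 9 libraries, per the file headers. All 17588 are typed as mRNA in the table, 2 are at 0 in all libraries, and replicates were not pooled. The aligner, the counting tool and the annotation are not given in the sources used here. The submitters' processing notes name the build GRCm38, a mouse build, although the samples are labelled rat. Of the gene identifiers 16396 (93.2%) were found in a rat GRCr8 gene table, so the identifiers are those of rat genes; the build behind the alignment was not settled and no coordinates are given. Genes are named by the symbols of the authors' table, some of which are older names (Lect1 for Cnmd, Ctgf for Ccn2).

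The table holds no counts. Steps between the lowest values of rarely seen genes put the worth of 1 read, relative to the first control library, at 0.967 to 1.07. This rests on only 15 to 29 genes in each other library, so it is a rough comparison of depth. The absolute depth stayed unknown and no count test was run. Genes that every cell uses, such as Hprt1 and Polr2h, are at 0 in some libraries and above 5 FPKM in others of the same group, so a 0 can be a failed estimate. No fold is given against a group listed at 0. Genes of multigene families with near-identical copies (major histocompatibility and metallothionein genes) are uncertain, since the authors' counting could have split their reads.

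Groups were taken from the sample titles. Genes with FPKM of at least 1 in at least 3 of the 9 libraries were tested (11732 genes) on log2(FPKM + 1), with a pseudocount of 1 and no further scaling. A fold of at least 2 means a log2 change of at least 1 on this scale, which understates the change of low genes, whereas folds printed beside FPKM values are ratios of mean FPKM. limma (version 3.58.1, R 4.3.3) was fitted to all 9 libraries with a mean-variance trend, two-sided tests and Benjamini-Hochberg adjustment within each of 3 comparisons; a gene was called at an adjusted p under 0.05. The prior degrees of freedom were 3.64. Figures were drawn with matplotlib 3.10.9. No test of the difference between comparisons was made other than the comparisons named.

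The 32 gene lists, the 16 single genes fixed in advance, the groups, tests, alternatives and the rule for named genes were chosen before the data were examined. The rule took, per comparison, the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 FPKM in the higher group, no overlap between the groups' libraries and a symbol that is not a placeholder, up to 4 members of each list with the smallest p, the fixed genes, and, for genes called in both comparisons in opposite directions, 10 per direction with the smallest larger adjusted p. Members named because a count of 5 or fewer was given, and some further list members, were chosen after their values were seen. Lists covered proteases, protease inhibitors, cartilage, hypertrophy, fibroblastic matrix, cytokines, NF-κB, prostaglandin and nitric oxide synthesis, complement, interferon, antigen processing, inflammasome, TGF-β, growth factors, Wnt, cell cycle, p53, senescence, NRF2, hypoxia, cholesterol, unfolded protein response, heat shock, immediate-early genes and markers of 8 other cell types. Lists with at least 3 tested members (30 of the 32) were tested with camera at a preset correlation of 0.01, which compares a list with the other genes. Beside it stand camera with an estimated correlation and fry, which tests whether the members move on balance in 1 direction. List p-values were adjusted over the lists of a comparison.

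The gene test was checked on simulated data with known changes among the 11732 genes. For IL-1β against control it recovered 52.0%, 96.0%, 98.0% and 100.0% of genes changed by 0.25, 0.5, 1 and 2 log2. For co-culture against IL-1β it recovered 59.6%, 95.0%, 99.0% and 100.0%, and for co-culture against control 38.8%, 92.0%, 98.0% and 98.0%. Of the calls 5.88%, 4.62% and 3.55% fell on unchanged genes. The simulated noise was normal and independent, with the spreads of the fit. Few genes were changed and no library was shifted as a whole, so the rates in the real data may differ. The alternatives tried were pseudocounts of 0.1 and 0.5, no filter, a filter on mean FPKM of 5, rescaling to a common sum (TPM), median-of-ratios scaling, quantile normalization, no trend, a robust fit (with list tests on the z-scores of its statistics), only the 6 libraries compared, a replicate block, and leaving out each library. The values of 1 list member are not reported here. No library was left out of the main results and no column of the table was unused.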

Results

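Messenger RNA of rat primary chondrocytes, the cells that make and maintain cartilage matrix, was sequenced in 9 libraries. They fall into 3 groups of 3: a control group in routine culture, a group given interleukin-1β (IL-1β, an inflammatory cytokine used to provoke cartilage breakdown in culture), and a group that was given IL-1β and then shared its culture with dermal fibroblasts. In the co-culture the chondrocytes lay in the lower chamber of a transwell and the fibroblasts in the upper chamber, and the libraries are those of the chondrocytes. Levels are FPKM (sequenced fragments scaled to transcript length and to the library's total). They are given as mean ± SD with n = 3 libraries per group. FPKM summed to between 771058 and 782435 in the control libraries, 796262 and 832248 in the IL-1β libraries and 809839 and 811665 in the co-culture libraries. The control libraries thus had the lowest sums, and the main tests were not rescaled for this. Between 11337 and 11522 genes reached 1 FPKM in a library, and the absolute depth is unknown. Nothing in the labels says that the replicates were separate animals or cultures, so the p-values measure the spread between these libraries, which may be technical.

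Libraries of 1 group resembled each other more than libraries of different groups. Across the 11732 tested genes, Pearson's r of log2(FPKM + 1) was 0.994 to 0.995 within groups, 0.961 to 0.963 between control and IL-1β, 0.978 to 0.982 between control and co-culture, and 0.987 to 0.990 between IL-1β and co-culture (genes are not independent replicates). The first principal component held 70.005% of the variance. On it the control libraries lay at -32.0 to -31.6, the IL-1β libraries at 25.1 to 26.9 and the co-culture libraries between them at 3.82 to 7.80. The second held 7.61% and set the co-culture libraries, at -11.3 to -10.5, apart from the other groups. The median coefficient of variation of genes at 10 FPKM or more was 3.24% in control, 3.34% in IL-1β and 3.92% in co-culture libraries.

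The first comparison, IL-1β against control, asked how the chondrocytes responded to the cytokine. Genes of inflammation and matrix breakdown rose and genes of cartilage matrix fell. The acute-phase protein gene Lcn2 rose from 12.4 ± 1.44 to 2708 ± 98.9 FPKM (219-fold) and the stromelysin gene Mmp3 from 35.7 ± 3.00 to 2153 ± 109 (60.3-fold). The collagenase gene Mmp13 rose from 21.4 ± 1.28 to 446 ± 30.3 (20.8-fold) and the cytokine gene Il6 from 5.64 ± 0.311 to 179 ± 15.3 (31.8-fold). Type II collagen (Col2a1) fell 6.19-fold, from 1042 ± 31.96 to 168 ± 4.45, link protein (Hapln1) fell 7.67-fold, from 102 ± 1.04 to 13.2 ± 1.52, and aggrecan (Acan) fell 3.18-fold, from 285 ± 7.65 to 89.5 ± 2.22. In limma, 5479 of 11732 genes passed an adjusted p of 0.05, 3109 of them higher and 2370 lower with IL-1β. Of these, 497 changed at least 2-fold on the log2(FPKM + 1) scale, 340 higher and 157 lower. The split between higher and lower calls depended on the scaling: 2247 higher and 3186 lower with libraries rescaled to a common sum, 2291 and 3332 after quantile normalization, and 2723 and 2732 with median-of-ratios scaling.

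Of the 24 tested cytokine and chemokine genes, 22 rose and 0 fell, both over all genes and adjusted over the list alone. The median log2 change was 3.23 (camera adjusted p = 1.97e-18, and adjusted p = 0.0416 with an estimated correlation). The neutrophil chemokine Cxcl3 rose from 9.16 ± 0.554 to 1739.9 ± 88.99 FPKM, Ccl20 from 0.687 ± 0.268 to 280.0 ± 17.9 and Ccl2 from 379 ± 4.28 to 4032 ± 228. The colony-stimulating factors Csf3 and Csf2 rose from 0.0667 ± 0.0651 and 0.31 ± 0.269 to 93.8 ± 4.48 and 98.5 ± 5.25. All 21 tested NF-κB feedback and target genes rose (21 adjusted over the list alone; adjusted p = 5.41e-16). Sod2, a mitochondrial superoxide dismutase, rose from 58.1 ± 1.72 to 957 ± 30.3, and the inhibitor Nfkbia from 12.4 ± 0.439 to 110.0 ± 2.25. Of 14 prostaglandin and nitric oxide synthesis genes, 10 rose and 2 fell (the same adjusted over the list alone; adjusted p = 0.000348). Inducible nitric oxide synthase (Nos2) rose from 0.05 ± 0.01 to 34.7 ± 1.12, cyclooxygenase-2 (Ptgs2) from 27.9 ± 3.04 to 307 ± 3.19 and the prostaglandin E synthase Ptges from 39.6 ± 1.34 to 756 ± 38.9. Cyclooxygenase-1 (Ptgs1) and the prostaglandin-degrading enzyme Hpgd fell. Of 14 complement and acute-phase genes, 12 rose and 0 fell, as they did adjusted over the list alone (adjusted p = 6.05e-09). Complement C3 rose from 0.333 ± 0.0723 to 65.3 ± 1.28. Wfdc21, the only gene among the 10 largest rises that was listed at 0 in every control library, reached 65.5 ± 3.78 with IL-1β.

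Of 20 matrix-degrading protease genes, 14 rose and 3 fell (14 and 4 adjusted over the list alone; adjusted p = 1.39e-05). Mmp10 rose from 4.75 ± 0.367 to 300.4 ± 11.8 FPKM and the gelatinase gene Mmp9 from 0.88 ± 0.0794 to 124 ± 4.35. The aggrecanase gene Adamts5 rose from 6.65 ± 0.484 to 18.5 ± 0.284, and Adamts4 from 1.54 ± 0.2 to 2.54 ± 0.118. The 3 that fell were Mmp14, Mmp19 and the collagen-degrading cathepsin gene Ctsk. Of 10 protease inhibitors, 7 rose and 2 fell (also adjusted over the list alone; adjusted p = 0.0371, and adjusted p = 0.145 with an estimated correlation). Timp3, an inhibitor of metalloproteinases, rose from 9.84 ± 0.505 to 44.2 ± 0.92, and Timp2 and the collagen chaperone Serpinh1 fell. That list's call ended without IL-1β replicate 2 and in 2 other filter settings (adjusted p between 0.0519 and 0.145).

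Of 27 cartilage matrix and chondrocyte identity genes, 22 fell and 3 rose (23 and 3 adjusted over the list alone; median log2 change -1.49, adjusted p = 2.5e-13). Type IX collagen (Col9a1) fell from 76.1 ± 0.734 to 18.9 ± 0.221 FPKM, the matrix protein Comp from 61.9 ± 0.97 to 15.9 ± 0.55 and the chondrocyte transcription factor Sox9 from 6.64 ± 0.243 to 3.41 ± 0.365. The 3 that rose were Prg4, which encodes the joint lubricant lubricin (13.7 ± 0.189 to 284 ± 12.7), Sox5 and the chondroitin sulfotransferase gene Chst11. Among 24 fibroblastic matrix and dedifferentiation genes, 18 fell and 4 rose, the same adjusted over the list alone (median -0.84, adjusted p = 3.79e-10). Type I collagen (Col1a1) fell from 1973 ± 55.7 to 877 ± 32.1, smooth muscle actin (Acta2) from 665 ± 7.52 to 189 ± 3.66 and elastin (Eln) from 33.1 ± 2.45 to 5.59 ± 0.2. The 4 that rose were Lox, Fn1, Fbn1 and Postn. Of 8 hypertrophy and mineralization genes, 6 fell and 2, Spp1 and Vegfa, rose (also adjusted over the list alone; adjusted p = 0.056). That list passed in 5 other settings (adjusted p between 0.000202 and 0.0494), namely no filter, no trend, only the 6 libraries compared, fry and without IL-1β replicate 3 (0.0494). Col10a1, a marker of hypertrophic chondrocytes, stayed between 0.01 and 0.1 FPKM in all libraries. Of 18 Wnt pathway genes, 12 fell and 4 rose, also adjusted over the list alone (adjusted p = 0.0156; adjusted p = 0.0633 with an estimated correlation). The list call also ended with libraries rescaled to a common sum and with quantile normalization. Its direction turned with genes of mean FPKM 5 or more (adjusted p between 0.0515 and 0.61 over these settings).

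Hypoxia and glycolysis genes rose together: 22 of 25 rose and 1, P4ha1, fell (also adjusted over the list alone; median 0.62, adjusted p = 1.13e-10). The oxygen-sensing hydroxylase gene Egln3 rose from 2.15 ± 0.21 to 118 ± 0.917, and the glucose transporter gene Slc2a1 from 68.2 ± 1.77 to 141 ± 2.13. Of 23 NRF2 and antioxidant genes 18 rose and 2, Gpx3 and Nqo1, fell, likewise adjusted over the list alone (adjusted p = 1.2e-06). Heme oxygenase (Hmox1) rose from 142 ± 6.79 to 359.9 ± 16.1. Of 11 antigen processing genes 9 rose and 0 fell (10 and 0 adjusted over the list alone; adjusted p = 3.3e-05). The major histocompatibility genes among them belong to a multigene family and are uncertain. Of 15 interferon-stimulated genes 10 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.0241, and adjusted p = 0.0784 with an estimated correlation). That list call also ended under both other filters (adjusted p up to 0.183). The following lists did not pass with camera. Cell-cycle genes split 11 higher and 18 lower of 34 (11 and 19 adjusted over the list alone; adjusted p = 0.0665, and in the settings that passed 0.0043 with fry and 0.0494 without IL-1β replicate 3). Growth factors split 11 and 8 of 22 (adjusted p = 0.46), TGF-β and BMP response genes 11 and 10 of 26 (0.813) and p53 target genes 9 and 3 of 19 (0.262). Senescence and apoptosis genes split 6 and 6 of 18 (0.634). Adjusted over the list alone these were 11 and 8, 11 and 10, 10 and 4, and 8 and 6. Cholesterol synthesis genes split 7 and 2 of 22 (0.534), unfolded protein response genes 7 and 10 of 23 (0.204) and heat-shock genes 3 and 5 of 11 (0.251). Immediate-early genes split 7 and 6 of 16 (0.634) and inflammasome genes 4 and 1 of 6 (0.227). Adjusted over the list alone these were 7 and 2, 7 and 12, 3 and 5, 7 and 7, and 4 and 1. With fry, growth factors (adjusted p = 1.8e-05), p53 (0.000301), senescence (0.00016), cholesterol (0.00316) and inflammasome genes (2.78e-05) passed as higher. Unfolded protein response (0.00119) and heat-shock genes (1.8e-05) passed with fry as lower. TGF-β and BMP response genes and immediate-early genes did not pass with either test.

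Markers of other cell types were measured in the same libraries. All 8 tested skeletal muscle markers rose with IL-1β (8 adjusted over the list alone; median log2 change 0.89, adjusted p = 9.86e-06). The myosin light chain gene Mylpf rose from 80.1 ± 1.55 to 172 ± 10.99 FPKM, the skeletal actin gene Acta1 from 29.4 ± 2.41 to 88.5 ± 2.77 and the myogenic factor Myog from 12.4 ± 1.64 to 33.4 ± 0.694. Of 24 dermal fibroblast markers in the table, 6 fell below the filter and did not exceed 1.31 FPKM in any library. These were Dpp4, Pi16, Cd34, Entpd1, Clec3b and the entry named Ogn. The 18 tested dermal fibroblast markers all averaged at least 1 FPKM in the control chondrocytes, which the filter made likely. With IL-1β 8 of them rose and 6 fell (8 and 7 adjusted over the list alone; adjusted p = 0.549). Decorin (Dcn) stood at 32.4 ± 1.75 and 324 ± 10.8 and lumican (Lum) at 87.8 ± 3.29 and 765 ± 26.1. Macrophage markers split 2 higher and 2 lower of 7 (adjusted p = 0.716), where the lower call of Laptm5 ended without any 1 of the 6 libraries (-0.37 to -0.32 log2). Osteoblast and osteoclast markers split 0 and 2 of 3 (0.204), keratinocyte markers 1 and 1 of 3 (0.813) and adipocyte markers 2 and 1 of 3 (0.44). Fabp4, a fatty acid carrier, rose from 16.7 ± 3.49 to 169.8 ± 14.3. Adjusted over the list alone only osteoblast and osteoclast markers differed, with 1 higher and 2 lower. With fry, dermal fibroblast (adjusted p = 2.52e-06) and adipocyte markers (2.63e-05) passed as higher and osteoblast and osteoclast markers (8.16e-05) as lower. Erg and Egfl7, the 2 of 11 listed endothelial markers above the filter, fell. The 9 below the filter did not exceed 0.59 FPKM in any library, so the 2 falls do not speak for endothelial cells. None of the 3 erythroid markers exceeded 0.22 FPKM. With an estimated correlation 11 of the 14 list calls of this comparison held, at camera adjusted p between 0.0334 and 0.0416. Those lost were protease inhibitors, interferon-stimulated genes and Wnt pathway genes.

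**Figure D1:**
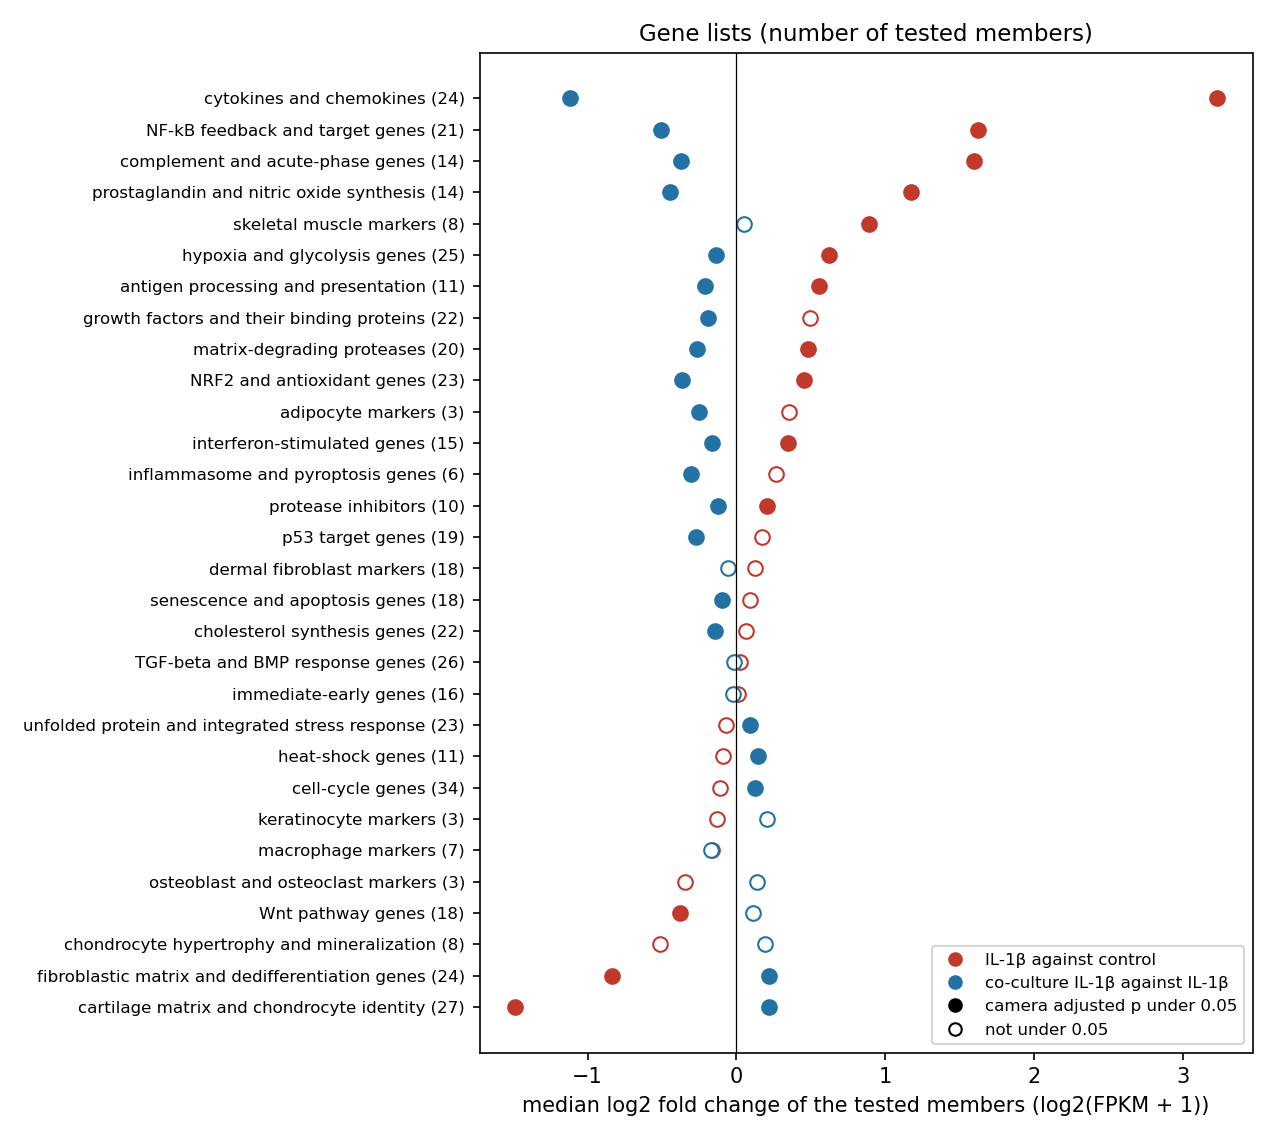
Median log2 fold change of the tested members of each gene list (horizontal axis, log2(FPKM + 1) scale), for IL-1β against control in red and co-culture with IL-1β against IL-1β in blue; filled points have a camera adjusted p under 0.05 and the number of tested members stands in brackets. The cytokine list lies at 3.23 with IL-1β and at -1.12 with co-culture, and the cartilage list at -1.49 and 0.22.

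The main comparison, co-culture with IL-1β against IL-1β alone, asked what the presence of dermal fibroblasts changed in stimulated chondrocytes. Inflammatory and matrix-degrading genes fell and several cartilage matrix genes rose. Mmp13 fell 5.22-fold, from 446 ± 30.3 to 85.5 ± 13.5 FPKM, and Il6 3.02-fold, from 179 ± 15.3 to 59.5 ± 6.58. Nos2 fell 22.6-fold, from 34.7 ± 1.12 to 1.54 ± 0.654, and Il23a, a subunit of interleukin-23, 67.6-fold, from 53.6 ± 4.49 to 0.793 ± 0.359. Hapln1 rose 2.34-fold, from 13.2 ± 1.52 to 31.003 ± 2.31, Acan 1.57-fold, from 89.5 ± 2.22 to 140.4 ± 6.67, and Col2a1 1.49-fold, from 168 ± 4.45 to 250.0 ± 18.3. In limma 2581 genes passed an adjusted p of 0.05, 1393 higher and 1188 lower. At least 2-fold changes were nearly all falls: 91 of 95 such genes were lower and 4 higher (135 of 150 and 15 with a pseudocount of 0.1). Under the alternatives other than leaving out a library, 47.2% to 58.0% of the called genes were higher.

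Of 24 cytokine and chemokine genes, 21 fell and 0 rose (22 and 0 adjusted over the list alone). The median log2 change was -1.12 (camera adjusted p = 4.37e-25, and adjusted p = 0.0335 with an estimated correlation). Csf3 fell from 93.8 ± 4.48 to 7.03 ± 1.28 FPKM, Csf2 from 98.5 ± 5.25 to 7.78 ± 3.62 and Cxcl2 from 213 ± 12.9 to 20.99 ± 5.46. Ccl20 fell from 280.0 ± 17.9 to 54.5 ± 10.5 and Ccl2 from 4032 ± 228 to 1872 ± 153. NF-κB feedback and target genes fell in 17 of 21 cases (19 adjusted over the list alone; median -0.51, adjusted p = 7.17e-18). Under co-culture Sod2 stood at 431 ± 41.7 and Nfkbia at 53.2 ± 6.70. Of 14 prostaglandin and nitric oxide genes 8 fell and 2, Ptgs1 and Hpgd, rose, also adjusted over the list alone (adjusted p = 6.12e-06). Ptgs2 fell to 131 ± 6.73 and Ptges to 292 ± 23.7. Of 14 complement and acute-phase genes 8 fell and 0 rose, also adjusted over the list alone (adjusted p = 8.61e-08), Lcn2 among them at 994 ± 110.0. Interferon-stimulated genes fell in 5 of 15 cases (5 adjusted over the list alone; adjusted p = 0.00338) and antigen processing genes in 6 of 11 (6; 8.21e-05). Among the interferon-stimulated genes, Usp18 lost its call without any 1 of the 6 libraries but co-culture replicate 1 (-0.35 to -0.23 log2 over 7 settings) and Stat2 without IL-1β replicate 3 (-0.17). Inflammasome genes fell in 3 of 6 (3; 0.000779, and adjusted p = 0.0751 with an estimated correlation), the 3 being Nlrp3, Il1b and Ninj1.

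Of 20 matrix-degrading proteases, 11 fell and 2, Mmp14 and Mmp19, rose (12 and 3 adjusted over the list alone; adjusted p = 1.75e-07). Mmp3 fell to 1048 ± 51.3 FPKM, Mmp9 to 38.4 ± 3.36, Adamts5 to 11.1 ± 1.18 and Adamts4 to 1.75 ± 0.189. Protease inhibitors fell in 5 of 10 cases and rose in 0 (also adjusted over the list alone; adjusted p = 0.000822). Timp3 fell to 13.1 ± 1.57. Of 27 cartilage genes 14 rose and 2, Prg4 and Sox5, fell (18 and 4 adjusted over the list alone; median 0.22, adjusted p = 9.49e-05, and adjusted p = 0.0751 with an estimated correlation). Sox9 rose from 3.41 ± 0.365 to 4.52 ± 0.352, Comp from 15.9 ± 0.55 to 19.3 ± 1.10 and Col9a1 from 18.9 ± 0.221 to 23.5 ± 0.616, and Prg4 fell from 284 ± 12.7 to 123 ± 8.27. Of 24 fibroblastic matrix genes 16 rose and 5 fell, also adjusted over the list alone (median 0.22, adjusted p = 5.28e-06, and adjusted p = 0.0769 with an estimated correlation). Type III collagen (Col3a1) rose from 431 ± 6.95 to 599 ± 23.7 and Acta2 from 189 ± 3.66 to 284 ± 24.4. The smaller rise of Col1a1, by 0.14 log2 ± 0.04 (SE; adjusted p = 0.0264), lost its call in 8 settings, at 0.11 to 0.15 log2. Among these were leaving out IL-1β replicate 1 or 2 or co-culture replicate 1 or 2. Hypertrophy genes split 2 higher and 1 lower of 8 (4 and 1 adjusted over the list alone; adjusted p = 0.256). Ankh and Enpp1, which act in pyrophosphate metabolism, rose and Vegfa fell. With fry the hypertrophy list passed as higher (adjusted p = 0.00125).

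NRF2 and antioxidant genes fell as a group: 18 of 23 fell and 1, Gpx3, rose (18 and 2 adjusted over the list alone; median -0.37, adjusted p = 3.8e-14). Hmox1 fell from 359.9 ± 16.1 to 116 ± 3.96 FPKM, below its control level of 142 ± 6.79, and Srxn1, which repairs oxidized peroxiredoxins, from 34.8 ± 0.746 to 19.04 ± 0.622. Of 19 p53 target genes 13 fell and 2, Plk2 and Perp, rose, also adjusted over the list alone (median -0.27, adjusted p = 2.02e-06). The cell-cycle inhibitor Cdkn1a fell from 196 ± 5.07 to 119.9 ± 3.41 and the p53 ligase gene Mdm2 from 81.1 ± 0.796 to 51.4 ± 2.90. Gdf15, a stress-responsive secreted factor, fell 8.62-fold, from 9.89 ± 1.03 to 1.15 ± 0.385. Hypoxia and glycolysis genes fell in 14 of 25 cases and rose in 1, Slc2a3 (16 and 1 adjusted over the list alone; adjusted p = 3.63e-08). Cholesterol synthesis genes fell in 8 of 22 cases and rose in 0 (12 and 0 adjusted over the list alone; adjusted p = 5.08e-05). Cell-cycle genes rose in 19 of 34 cases and fell in 1, Ccne1 (24 and 1 adjusted over the list alone; median 0.13, adjusted p = 5.26e-07, and adjusted p = 0.0758 with an estimated correlation). The mitotic gene Cdc20 rose from 119 ± 4.70 to 153 ± 4.30 and Aurka from 41.3 ± 1.60 to 51.2 ± 2.36. Heat-shock genes rose in 5 of 11 cases and fell in 0 (6 and 1 adjusted over the list alone; adjusted p = 0.00818, and adjusted p = 0.0697 with an estimated correlation).

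Growth factors split 6 higher and 10 lower of 22 (6 and 11 adjusted over the list alone; adjusted p = 0.011, and adjusted p = 0.0977 with an estimated correlation). The epidermal growth factor receptor ligand Ereg fell from 91.3 ± 10.5 to 19.98 ± 2.72 FPKM and Igf1 rose from 3.32 ± 0.365 to 5.28 ± 0.127. Senescence and apoptosis genes split 2 and 6 of 18 (2 and 7 adjusted over the list alone; adjusted p = 0.045). Unfolded protein response genes split 11 and 3 of 23, also adjusted over the list alone (adjusted p = 0.0459). Both of these calls ended with an estimated correlation (adjusted p = 0.0859 for each). The senescence call also ended with the replicate block, median-of-ratios scaling or no trend, and without IL-1β replicate 1 or co-culture replicate 1. The unfolded protein call also ended with the filter on mean FPKM, median-of-ratios scaling, quantile normalization, no trend or only the 6 libraries compared. It ended too without IL-1β replicate 3 or co-culture replicate 1 or 3 (adjusted p up to 0.0859 and 0.184 for the lists over all settings that ended their calls). Wnt genes split 7 and 4 of 18 (8 and 4 adjusted over the list alone, camera adjusted p = 0.621, fry adjusted p = 0.0125 as higher). TGF-β and BMP response genes split 8 and 9 of 26 (9 and 10 over the list alone, camera adjusted p = 0.715). Immediate-early genes split 4 and 6 of 16 (5 and 6 over the list alone, camera adjusted p = 0.621).

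Dermal fibroblast markers did not pass as a list under co-culture. Of the 18 dermal fibroblast markers 3 (Twist1, Dlk1 and Sfrp4) rose and 4 (Dcn, Lum, Sfrp2 and Prrx1) fell (4 and 5 adjusted over the list alone; median -0.06, adjusted p = 0.0974). The list passed as lower with genes of mean FPKM 5 or more and with fry (adjusted p between 0.00219 and 0.0302). Of the 8 skeletal muscle markers 0 rose and 1, Acta1, fell (0 and 1 adjusted over the list alone; adjusted p = 0.809). Mylpf stood at 180.3 ± 11.7 FPKM and Myog at 36.7 ± 3.67. The Acta1 call ended in 5 settings, at -0.21 to -0.18 log2, among them leaving out IL-1β replicate 1 or 2 or co-culture replicate 2 or 3. Macrophage markers split 0 and 2 of 7 (0.33), osteoblast and osteoclast markers 0 and 1 of 3 (0.74) and keratinocyte markers 1 and 1 of 3 (0.715). Adjusted over the list alone these were 0 and 2, 2 and 1, and 1 and 1. With fry the macrophage list passed as lower (adjusted p = 0.00925). Leaving out 1 library ended several of the single-gene calls (log2 values over the settings that ended each). The macrophage marker Cd14 lost its call without IL-1β or co-culture replicate 1 or 2 (-0.18 to -0.16) and Acp5, the only lower osteoclast marker, without IL-1β or co-culture replicate 2 or 3 (-0.29 to -0.23). Sfn, the only lower keratinocyte marker, lost it without any 1 of the 6 libraries and in 4 other settings, the replicate block among them (-0.40 to -0.25). Adipocyte markers fell in 2 of 3 cases, Fabp4 to 42.9 ± 8.36 (3 adjusted over the list alone; adjusted p = 0.00605, and adjusted p = 0.0586 with an estimated correlation). The other, Lpl, lost its call in 7 settings (-0.23 to -0.19), among them without IL-1β replicate 2 or 3 or co-culture replicate 1, 2 or 3. Of the 2 endothelial genes 0 passed (1, adjusted over the list alone, was higher). Of the 21 list calls of this comparison, 12 held with an estimated correlation, at camera adjusted p between 0.0247 and 0.0449.

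**Figure D2:**
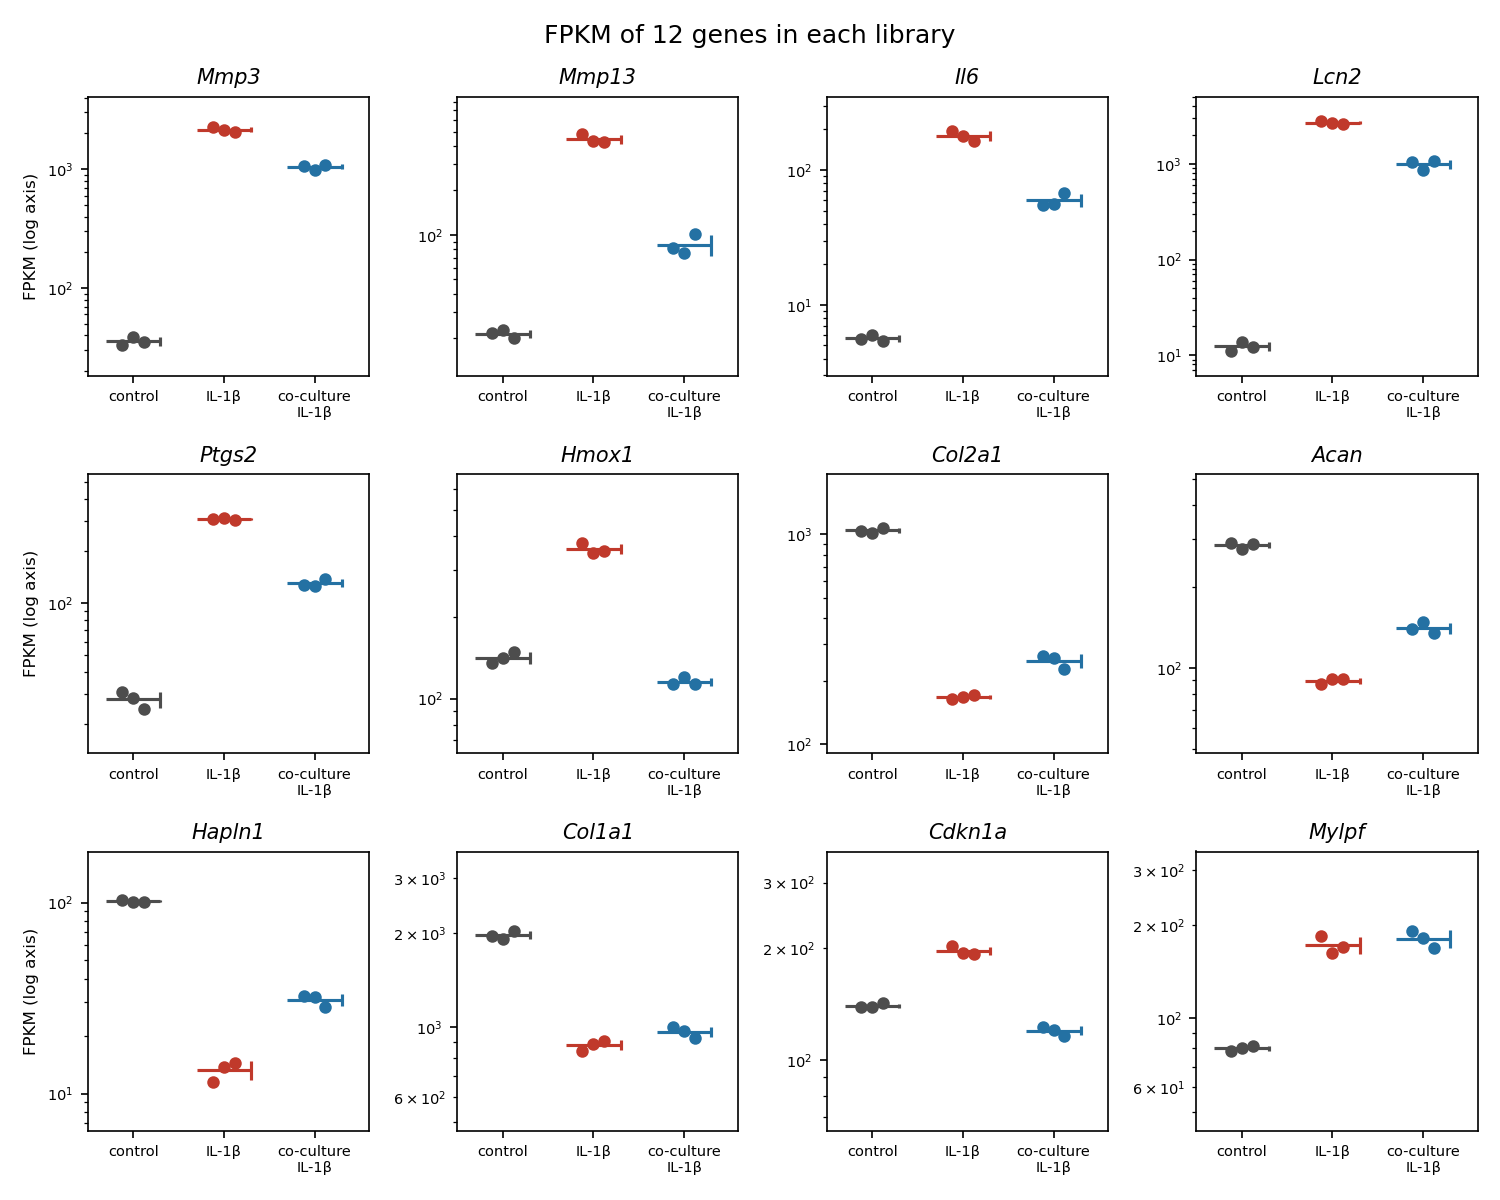
FPKM (log axis) of 12 genes in each of the 9 libraries; points are libraries, horizontal lines group means and vertical bars ± 1 SD (n = 3 per group). For Mmp3, Mmp13, Il6, Lcn2, Ptgs2, Col2a1, Acan and Hapln1 the co-culture libraries lie between the other groups, for Hmox1 and Cdkn1a they lie below both, and for Mylpf they overlap the IL-1β libraries.

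The genes that responded to IL-1β were set against their change under co-culture. Of genes called higher with IL-1β, 1071 were called lower under co-culture, and of genes called lower with IL-1β, 1042 were called higher. Independent lists of these sizes would share 315 and 281 genes. The 50 simulations with no co-culture effect gave 0.02 and 0 on average. Hardly any gene can be called under co-culture in them, so these counts had to lie near 0. They do not measure how far the shared IL-1β libraries raise the overlap of the calls. Calls with the same sign numbered 31 higher and 15 lower, where independent lists would share 369 and 240.0. Of the 340 genes raised at least 2-fold by IL-1β, 294 (86.5%) were called lower under co-culture, and of the 157 lowered at least 2-fold, 117 (74.5%) were called higher. By the smallest adjusted p in both comparisons, the genes that rose and then fell were led by Il23a, Hmox1 and Csf3. Next came the citrulline-recycling enzyme gene Ass1 (1.46 ± 0.1, 29.6 ± 0.48 and 7.41 ± 0.491 FPKM in control, IL-1β and co-culture), the aldo-keto reductase gene Akr1b8 (217 ± 10.7, 796 ± 48.1 and 268 ± 7.32) and Il11. The genes that fell and then rose were led by the interleukin-33 receptor gene Il1rl1 (678 ± 17.4, 205 ± 1.74 and 369.9 ± 19.7) and Susd5. Next came Tgfbi, which is induced by TGF-β (212 ± 1.21, 74.8 ± 2.26 and 116 ± 3.67), Txnip and the water channel gene Aqp1 (430.2 ± 2.47, 86.5 ± 2.86 and 133 ± 5.36). Across genes the covariance of the log2 changes was -0.104, against -0.00579 in the simulations, and r was -0.783 against -0.101. With different IL-1β libraries in both comparisons the covariance was -0.0956, -0.0955 and -0.0966 in the 3 possible splits. Part of the excess in the calls may still come from shared libraries.

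**Figure D3:**
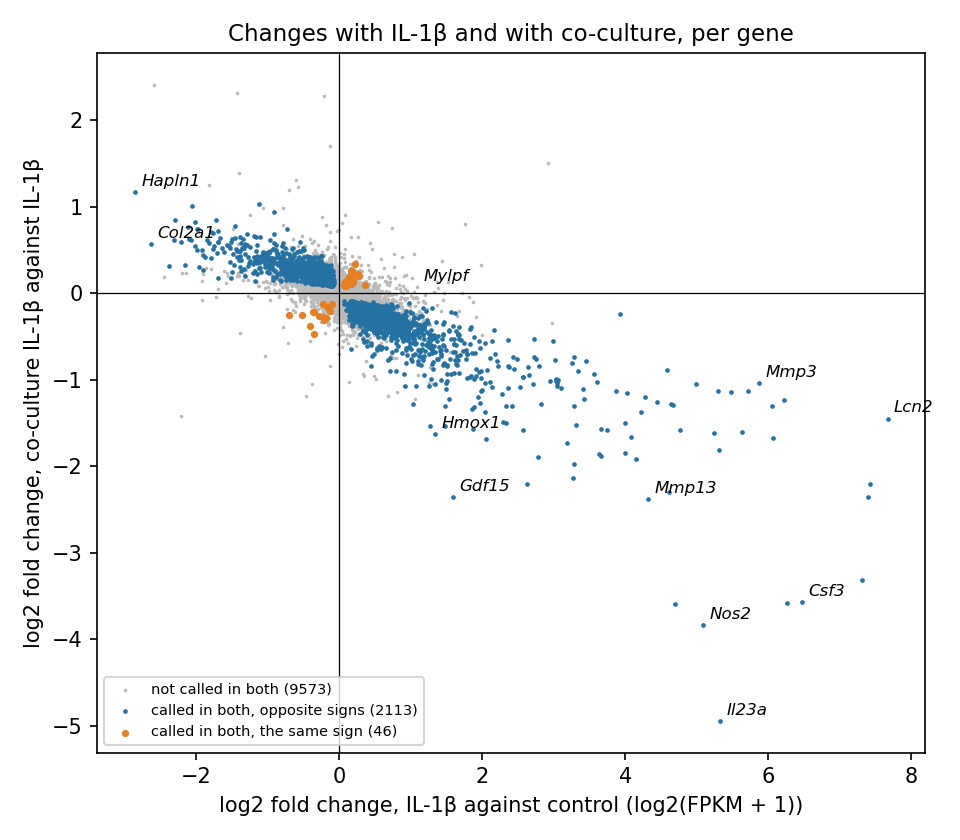
Log2 fold change with IL-1β against control (horizontal axis) and with co-culture against IL-1β (vertical axis) for each of 11732 genes, both on the log2(FPKM + 1) scale. Blue points are the 2113 genes called in both with opposite signs and orange points the 46 called in both with the same sign; the comparisons share the IL-1β libraries.

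The last comparison, co-culture with IL-1β against control, asked how far the co-cultured cells still differed from routine culture. Inflammatory genes remained above and cartilage genes below their control levels. Lcn2 was 80.4-fold higher than in control, Mmp3 29.3-fold, Il6 10.5-fold and Mmp13 3.99-fold. Col2a1 was 4.17-fold, Hapln1 3.28-fold and Acan 2.03-fold lower. Adamts4, at 1.75 ± 0.189 against 1.54 ± 0.2 FPKM, did not differ detectably (adjusted p = 0.337), and Cdkn1a was lower than in control (119.9 ± 3.41 against 139.8 ± 1.97, adjusted p = 0.000388). In limma 3981 genes passed, 2554 higher and 1427 lower, and 240 of them by at least 2-fold, 163 higher and 77 lower (399 with a pseudocount of 0.1, 273 and 126). Scaling turned the split: 1544 higher and 2006 lower with a common library sum, 1641 and 2076 after quantile normalization, and 1854 and 1869 with median-of-ratios scaling.

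Of the tested lists, 22 of 24 cytokine genes (adjusted p = 1.88e-18), 19 of 21 NF-κB genes (2.78e-16) and 12 of 14 complement and acute-phase genes (4.53e-10) were higher in co-culture than in control. So were 21 of 25 hypoxia and glycolysis genes (1.26e-10) and all 8 muscle markers (1.78e-07). Of these lists 1 hypoxia gene, P4ha1, was lower, and 22, 20, 12, 22 and 8 were higher adjusted over the list alone. Proteases split 12 higher and 3 lower (13 and 4 adjusted over the list alone; 0.000146), prostaglandin and nitric oxide genes 9 and 2 (9 and 2; 0.00181) and antigen processing genes 9 and 0 (9 and 0; 0.000372). Cartilage genes split 2 higher and 23 lower of 27 (2 and 23 adjusted over the list alone; 3.49e-19) and fibroblastic matrix genes 4 and 19 of 24 (4 and 20; 4.48e-15). Wnt genes split 3 and 10 of 18 (3 and 10; 0.00711, turning direction with genes of mean FPKM 5 or more, adjusted p = 0.557). p53 target genes split 2 and 7 (2 and 7 adjusted over the list alone; adjusted p = 0.0178, and adjusted p = 0.165 with an estimated correlation). Cholesterol genes split 1 and 6 (1 and 6; 0.016, and adjusted p = 0.0602 with an estimated correlation), and osteoblast and osteoclast markers 0 and 2 of 3, Sp7 and Ctsk (0 and 2; 0.0312, and adjusted p = 0.112 with an estimated correlation). The osteoblast and osteoclast call also ended with median-of-ratios scaling or quantile normalization, and without control replicate 3 or co-culture replicate 3 (adjusted p between 0.0501 and 0.112 over the settings that ended it). Of the 14 list calls of this comparison, 11 held with an estimated correlation, at camera adjusted p between 0.0304 and 0.0472.

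The other lists did not pass with camera in this comparison. With fry, NRF2 and antioxidant (adjusted p = 0.00118), protease inhibitor (3.1e-05), interferon-stimulated (0.000216), cell-cycle (0.0119) and growth factor genes (0.0142) passed as higher. So did dermal fibroblast (3.08e-05) and keratinocyte markers (0.0353), and macrophage markers (0.00303) passed as lower. The rest did not pass with fry either. NRF2 and antioxidant genes split 10 higher and 7 lower of 23 (12 and 7 adjusted over the list alone; 0.794), protease inhibitors 4 and 2 (5 and 2; 0.32) and interferon-stimulated genes 5 and 1 (5 and 1; 0.32). Inflammasome genes split 3 and 2 (3 and 2; 0.995), and hypertrophy genes 2 and 5 (2 and 6; 0.0671, and 0.00871 with no filter). Growth factors split 10 and 9 (10 and 9 adjusted over the list alone; 0.937), TGF-β and BMP genes 9 and 8 (9 and 8; 0.487) and cell-cycle genes 13 and 5 (13 and 8; 0.862). Senescence genes split 4 and 5 (4 and 6; 0.338), unfolded protein genes 8 and 5 (10 and 5; 0.951), heat-shock genes 6 and 3 (6 and 3; 0.937) and immediate-early genes 4 and 8 (4 and 8; 0.166). Fibroblast markers split 6 and 5 (6 and 5 adjusted over the list alone; 0.908) and macrophage markers 2 and 2 (2 and 2; 0.326). Keratinocyte markers split 1 and 0 (1 and 0; 0.937), adipocyte markers 1 and 1 (2 and 1; 0.976), and both endothelial genes were lower (2 adjusted over the list alone). The median, mean and camera direction differed in sign for some lists that did not pass: TGF-β and BMP, immediate-early and keratinocyte genes with IL-1β, immediate-early genes in co-culture against IL-1β, and TGF-β and BMP, growth factor, senescence, unfolded protein and heat-shock genes in co-culture against control. Of the 10 largest rises and 10 largest falls in this comparison, Rabif and Nfs1 are uncertain. Rabif was listed at 0 in every control library and in 1 IL-1β library. The Nfs1 control level was 5.96 ± 7.51, with an SD larger than the mean, and its call was lost without co-culture replicate 1, 2 or 3 (-1.84 to -1.65 log2 over the settings that ended it).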

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

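No alternative in this part was chosen after its result was seen. Most results for the named genes and the lists kept their direction and their side of the threshold. Of 7357 single-gene values of the named genes under the alternatives 7273 did, 70 lost a call, 14 gained one and 0 reversed. Of 1698 list values 1624 did, 40 lost a call, 30 gained one and 4 reversed. A sign change between values that were not called in either setting was counted as unchanged. The named genes were picked for large changes or small p, or fixed in advance, so they do not stand for all called genes. Rescaling to a common sum kept 4617 of the 5479 genes called with IL-1β against control. It kept 2313 of 2581 in co-culture against IL-1β and 2971 of 3981 in co-culture against control. Genes called with IL-1β against control numbered 4355 to 5769 over the alternatives (4804 to 4897 leaving out 1 library), in co-culture against IL-1β 2165 to 2620 (1916 to 2482) and in co-culture against control 3287 to 3992 (3252 to 3679). At least 2-fold changes numbered 332 to 707, 74 to 150 and 183 to 399 (495 to 517, 86 to 108 and 232 to 252 leaving out 1 library). The largest of these came with a pseudocount of 0.1, which gave 150 genes in co-culture against IL-1β and 399 in co-culture against control. A smaller pseudocount by its construction raises the folds of low genes. Opposite calls numbered 1863 to 2232 (1658 to 1982 leaving out 1 library), and calls among the fixed single genes 39 to 44 (43 to 44). Calls among the named genes numbered 373 to 417 (406 to 415) and list calls 34 to 73 (47 to 50), the lowest with an estimated correlation and the highest with fry. The direction of 4 list values turned. Wnt pathway genes were called against control with IL-1β and with co-culture, and with mean FPKM of at least 5 they turned direction and were not called (adjusted p = 0.61 and 0.557). Adipocyte markers and growth factors were not called in co-culture against control (0.976 and 0.937), and were called in the other direction with no filter (0.0224) and with fry (0.0142). The cause was not tested. Replicate numbers shared by the groups did not pair the libraries: residuals of libraries with the same number correlated between -0.0907 and 0.0855, and 1 of 9 libraries correlated best with its own number in both other groups. With the replicate block 5201, 2266 and 3681 genes were called in the 3 comparisons, 501, 95 and 241 of them by at least 2-fold, and 1881 in opposite directions. There were then 48 list calls, 43 calls of fixed genes and 414 of named genes. The absolute depth is unknown and no counts were used, so how far depth limits the calls of low genes was not measured.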

Other observations

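The tests of a single mixing share, of fibroblast RNA, of scaling for the lower and the higher genes apart, of p53, NRF2 and ribosome biogenesis genes, the same test over all lists, and both tests of muscle markers were chosen only after the results were seen.

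Genes differed in how much of the IL-1β change was left under co-culture. Measured as the share of the FPKM change from control that remained, the median was 44.2% for the 340 genes raised at least 2-fold and 79.4% for the 157 lowered at least 2-fold. On the log2 scale these were 62.2% and 69.9%, so the size of the difference between rises and falls depends on the scale. On the FPKM scale 0.795% ± 0.441 (SE) of the rise was left for Il23a, 4.29% ± 1.09 for Nos2, 7.43% ± 0.815 for Csf3, 7.61% ± 2.14 for Csf2 and 9.68% ± 1.52 for Cxcl2. It was 15.1% ± 1.94 for Mmp13, 19.3% ± 2.29 for Ccl20, 30.99% ± 2.70 for Il6, 36.9% ± 1.47 for Ptgs2 and 47.8% ± 1.99 for Mmp3. The order of genes depends on the scale too: on the log2 scale these shares were 7.13%, 24.4%, 44.8%, 42.8% and 54.7%, and 44.9%, 68.1%, 66.8%, 64.2% and 82.3%, so that Csf3 and Mmp13 no longer differed by much and Cxcl2 lay above Mmp13. Of the falls, 73.9% ± 2.11 was left for Acan, 79.9% ± 1.71 for Hapln1 and 90.6% ± 1.25 for Col2a1 (61.2%, 58.95% and 78.4% on the log2 scale). The median for raised genes on the FPKM scale was 44.4%, 40.1% and 48.1% in co-culture replicates 1, 2 and 3.

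The first pattern is that genes changed by IL-1β lay back toward control in the co-culture libraries. The tables argue against the shared IL-1β libraries as its cause, since with genes picked from 1 IL-1β library and measured against the others at least 91.6% still had the opposite sign (91.8% and 94.4% in the other splits). They argue against 1 mixing share of control-like and IL-1β-like RNA, since 43.5% of the 340 raised genes (148) lay more than 3 SE from the median share. Some dermal fibroblast RNA in the lysates stays open: the cartilage list, which such RNA should lower, and the fibroblastic matrix list, which it should raise, both had a median log2 change of 0.22 (14 higher and 2 lower, and 16 and 5; adjusted p = 0.0751 and 0.0769 with an estimated correlation), the fibroblastic list had fallen with IL-1β (18 of 24) and lay below control in co-culture (19 of 24), and dermal fibroblast markers went both ways (3 higher and 4 lower, median -0.06). A factor from the fibroblasts that dampens the response and a shorter or weaker exposure to IL-1β under co-culture also stay open, and neither was tested, since no group had co-culture without IL-1β or an insert without fibroblasts.

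The second pattern is a set of genes outside both other groups in the co-culture libraries: 81 were lower and 221 higher than in control and in IL-1β, against 9.92 and 17.9 on average in 50 simulations where co-culture lay between the others; other scalings turned the balance, with 106 lower and 82 higher for a common library sum, 114 and 103 for median-of-ratios scaling and 115 and 103 for quantile normalization. The tables argue against shared co-culture libraries as its cause, since of genes picked from 2 replicate numbers at least 72.6% lay outside on the same side in the number left out (167 of 230 without number 1, 71 of 79 without number 2, 64 of 77 without number 3). The lowest share of these genes found again under another scaling was 49.3%, with a common sum (72 of 81 lower and 77 of 221 higher genes, or 34.8% of the higher); the lowest for the lower genes alone was 85.2%, with quantile normalization (69 of 81), so scaling may account for much of the higher set (7 of 43 genes with ribosome biogenesis symbols stood in it, but these symbols were picked after that set was seen, so their two-sided Fisher's exact p of 1.39e-05 tests nothing). Among the lower genes stood 6 of 23 NRF2 and antioxidant genes (Hmox1, Nqo1, Srxn1, Gclc, Gclm and Me1, two-sided Fisher's exact p = 8.25e-09). So did 5 of 19 p53 target genes (Cdkn1a, Mdm2, Gadd45a, Eda2r and Plk3, two-sided Fisher's exact p = 1.49e-07). Over 60 such tests of all lists the adjusted p were 4.95e-07 and 4.48e-06. The only other list to pass was that of heat-shock genes, with 3 among the higher (Hspa8, Hspd1 and Hspe1, adjusted p = 0.0195). A gene in the lower set also had to fall against IL-1β, as 18 of 23 NRF2 and 13 of 19 p53 genes did. The tests set it against all tested genes and treat genes as independent. Their p-values thus do not by themselves show that the lists lay below control. As a whole list, NRF2 and antioxidant genes did not lie below control in co-culture. They split 10 higher and 7 lower of 23 (median log2 change 0.08, camera adjusted p = 0.794, fry adjusted p = 0.00118 as higher). The p53 list split 2 and 7 of 19 (camera adjusted p = 0.0178, 0.165 with an estimated correlation, fry adjusted p = 0.00173 as lower). As a hypothesis, co-culture may lower some NRF2 and p53 target genes apart from its effect on the IL-1β response. Without co-cultured cells free of IL-1β this stays untested.

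The third pattern is that skeletal muscle markers rose with IL-1β and, unlike most raised genes, stayed up under co-culture. The rises differed between markers, and 5 of the 8 lay more than 3 SE from the median ratio (Acta1 3.01-fold, Ckm 3.30-fold, Myog 2.70-fold, Des 1.79-fold and Myod1 1.31-fold). A larger share of muscle-lineage cells stays open all the same, since a single factor for all markers would need cells of 1 fixed profile and no expression of these genes in other cells, which was not measured. The median share of the rise left was 108%, above 99.99% of 10000 random lists of raised genes matched on the size of the rise (middle 95% from 37.1% to 69.3%), which describes the pattern and tests no explanation, since the markers were singled out for staying up. A change of state within muscle-lineage cells stays open as well, and no biological explanation was tested.

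For the counts of called genes and lists, the 10 splits of 6 libraries are too few for a share under 0.05, and the real split is 1 of them. For IL-1β against control the real counts and the highest of other splits were 5479 and 0 genes, 497 and 0 with at least 2-fold changes, and 14 and 12 lists. For co-culture against IL-1β they were 2581 and 1, 95 and 1, and 21 and 14. For co-culture against control they were 3981 and 2, 240 and 2, and 14 and 8. Of 100 arrangements of the 9 libraries, 3 gave at least 2113 opposite calls, the real one being 1 of the 3. That share lies under 0.05, but the other arrangements that were as large split the groups and reached up to 2610. A count of this size is thus not particular to the real groups, and the share does not exclude chance.

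Some entries were erratic. In 40 genes a library at or below 0.1 FPKM and another at or above 5 FPKM stood in the same group, Hprt1 (0, 0 and 0 in control; 2.21, 11.2 and 0 with IL-1β; 15.1, 0 and 11.9 in co-culture) and Polr2h (13.4, 0 and 12.9; 19.4, 0 and 6.4; 18.0, 13.9 and 0) among them. An entry named Ogn lay between 0 and 0.21 FPKM in all libraries, while an entry named gene-Ogn averaged 23.4 ± 0.605 in control, 5.17 ± 0.457 with IL-1β and 9.31 ± 0.246 in co-culture.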
